A study of Mus musculus with 8 samples.

How the data were processed

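RNA was measured by bulk RNA sequencing in outflow veins of arteriovenous fistulas from C57BL6J mice with a chronic kidney disease model. The fistula joined the carotid artery and the jugular vein 28 days after kidney disease was induced, and veins were taken 3 days after the fistula was made. In the MSC group, 250000 mesenchymal stem cells (MSCs) from a C57 donor of the same sex were laid on the outer layer (adventitia) of the outflow vein, and the other group received vehicle. Per the labels' protocols, 0.5 µg of total RNA per sample went into a TruSeq V2 library kit. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the gene annotation, any use of strand and any filter are not given in the sources used here.

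The authors deposited RPKM values (reads per kilobase of gene model per mega-read), 1 column per sample with no pooling. Which reads make up that total is not given in the sources used here. The table held 23358 gene rows, of which 69 shared 26 symbols and were kept as separate rows. In all, 3663 genes were at 0 in every sample and 19695 were above 0 in at least 1. RPKM values are whole reads times a factor set by gene and sample, so low values step in multiples of 1 read. Those steps returned whole reads for 100.0% of the 143006 values above 0, with a tolerance of 0.001 reads. A gene above 0 in only 1 sample meets this whatever its value, so the share says more for genes above 0 in all samples. All 16164 of those were returned whole. The reads came to 26.9 to 38.2 mega-reads (M) assigned to genes per sample, a lower bound where a gene's reads share a common factor. In simulated RPKM values, 99.7% of the 2498 genes with reads in at least 3 samples were returned exactly.

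RPKM are not counts, so the main test used log2(RPKM + 1) in limma 3.58.1 (R 4.3.3) with a mean-variance trend, no covariate and no block. It was 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, on the 12129 genes with a mean of at least 1 RPKM over all 8 samples. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. In data simulated from the same 12129 genes with 200 of them changed, the MSC against vehicle test recovered 91% of genes changed by 1 log2 unit and 94% of those changed by 2. Among its simulated calls 6.57% were unchanged genes, and a simulation with no change gave 0 calls of genes and 0 of lists. The simulated noise was drawn independently for each gene. These values therefore cannot tell how the tests behave where genes, such as members of a list, vary together.

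Gene lists were fixed before the data were examined: 41 lists with 1005 different genes, of which 994 were found in the table, 13 of them under an older symbol. The 40 lists with at least 4 genes tested were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01. The keratinocyte list had 1 gene tested and got no test. Each list was also tested by camera with an estimated correlation, by fry, and by an exact permutation test of its mean score over all assignments of 4 of 8 samples, whose smallest 2-sided p is 0.0286. Separation of the groups was tested over the 35 splits of 8 samples into 4 and 4, using the ratio of between-group to within-group sums of squared Euclidean distance.

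Genes were named by a rule set before the data were examined. The 12 largest positive and 12 largest negative log2 fold changes were taken among genes past the threshold whose 4 MSC samples lay on one side of all 4 vehicle samples. Where fewer than 5 passed in a direction, genes with the smallest unadjusted p were added until 5 and are stated as not passing. The rule also took up to 4 members per list by unadjusted p, of which part are printed, and every gene of the venous stenosis list. Results of some single genes are not reported; they stay in the tests and counts. Coordinates are those of GENCODE vM21 on GRCm38, the assembly behind mm10, counted from 1, and were found for 84 of 84 genes checked.

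Alternatives covered the pseudocount, the filter on low values, the scaling of samples, a replicate block, sample weights, the variance trend, each sample left out in turn, other thresholds, other list tests and another distance. Added after the data had been seen were limma voom on the recovered reads, the adipocyte or skeletal muscle score as a covariate, and a fit without genes that follow skeletal muscle. Intervals cover 95%. The chi-square per degree of freedom was 32.8 for the closest replicate pair (MSC 2 and MSC 3), above the counting noise of 1 library sequenced again. It does not tell whether samples came from separate animals, and all 8 were kept as replicates of their group.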

Results

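Outflow veins of carotid to jugular fistulas were compared between 4 samples that had received MSCs on the vein's outer surface and 4 that had received vehicle. All came from mice with a chronic kidney disease model, 3 days after the fistula was made. The gene reads recovered from the deposited RPKM values came to 33.3, 32.3, 32.3 and 26.9 M (M, mega-reads) in the vehicle samples and 29.9, 35.1, 38.2 and 32.5 M in the MSC samples. The labels do not say whether each sample came from its own animal, so the p-values measure the spread between these samples. The series title names venous stenosis, the narrowing of the fistula vein, as the condition the cell treatment is meant to act on. The comparison asks which genes differ in the sampled vein after treatment. The cells came from a C57 donor of the same sex, so any of their RNA in the samples cannot be told apart from the recipient's.

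On average, samples resembled those of their own group more than those of the other, with exceptions. The median Spearman correlation over genes was 0.975 between MSC samples, 0.968 between vehicle samples and 0.960 between groups, but MSC replicate 3 was closer to vehicle replicate 3 (0.9721) than to MSC replicate 4 (0.9696). Vehicle replicate 1 was closer to MSC replicate 3 (0.962) than to any vehicle sample (at most 0.959). The ratio of between-group to within-group variation was 2.66, against at most 1.71 for any other split, and the exact permutation test gave p = 0.0286, one-sided, the smallest that 35 splits allow. On the first principal component, with 33.6% of the variance, the MSC samples lay between 4.20 and 25.2 and the vehicle samples between -19.0 and -10.9. The second component, with 23.3%, set vehicle replicate 1 at 30.2 apart from the other vehicle samples, which lay between -15.8 and -9.25.

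**Figure D1:**
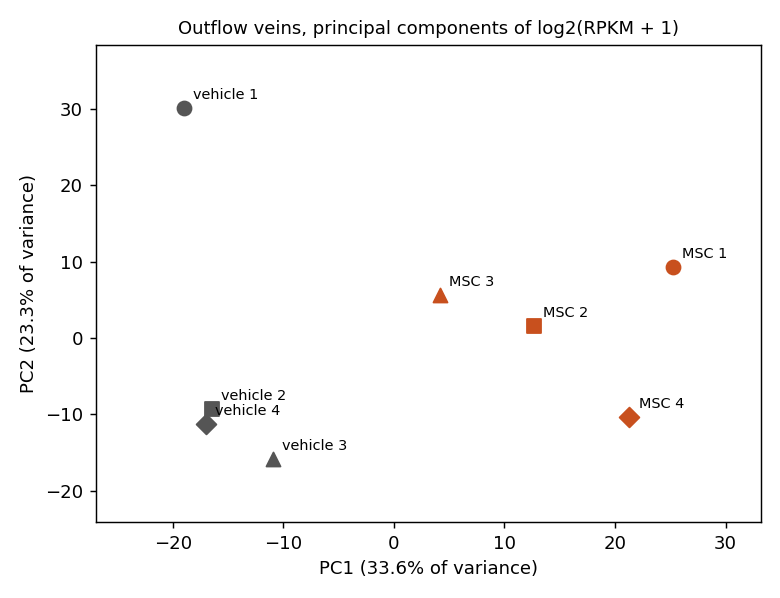
Each point is 1 sample on the first and second principal components of log2(RPKM + 1) over 12129 genes, with the share of variance on each axis. All MSC samples lie above 0 on the first component and all vehicle samples below 0.

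Of 12129 genes tested, 28 passed an adjusted p of 0.05 in limma: 3 were higher and 25 were lower in MSC veins, and in each of the 28 the groups did not overlap. The deepest fall was in Cyp2e1, a cytochrome P450 that oxidises ethanol and other small molecules. It went from 123 ± 51.4 RPKM in vehicle veins (SD, n = 4) to 12.8 ± 4.61 in MSC veins (SD, n = 4), a log2 fold change of -3.12 (SE 0.33, limma adjusted p = 0.0233). Acsl1, which activates long-chain fatty acids, fell from 75.8 ± 15.6 to 17.0 ± 8.83 RPKM (log2 fold change -2.21, SE 0.31, limma adjusted p = 0.041). Arxes2, an X-linked gene named for its expression in adipocytes, fell by 1.97 on the log2 scale. Its value is uncertain because a near-identical copy, Arxes1, can share its reads.

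Net1, a guanine nucleotide exchange factor, fell by 1.88 on the log2 scale, Fgl1, a fibrinogen-like protein, by a log2 fold change of -1.72, and Acss3, a short-chain acyl-CoA synthetase, by -1.50. Car5b, a mitochondrial carbonic anhydrase, had a log2 fold change of -1.45, the adenylyl cyclase gene Adcy5 one of -1.28 and the mitochondrial carrier gene Slc25a34 one of -1.25. Smoc1, a matrix protein, and Tshr, the thyrotropin receptor, both had -1.24, and Cish, a feedback inhibitor of cytokine signalling, had -1.23. The gene with the lowest adjusted p, Irf4, a transcription factor of lymphocytes, macrophages and adipocytes, was singled out after its values were seen. It fell from 5.48 ± 0.594 to 1.80 ± 0.359 RPKM (SD, n = 4 each; log2 fold change -1.22, SE 0.11, limma adjusted p = 0.0166). Adipocyte markers were lower in the same 4 samples. With the adipocyte score as a covariate, an alternative chosen after the data were seen, 0 of the 28 genes passed in limma (816 genes had an unadjusted p under 0.05). The covariate shrank some folds and widened the error of others: the log2 fold change of Acsl1 went from -2.21 (SE 0.31) to -1.01 (SE 0.20), and that of Irf4 from -1.22 (SE 0.11) to -1.17 (SE 0.19). In that fit limma also tested the slope on the adipocyte score within groups. Among the 28 genes, 1 had a slope adjusted over all genes, Acsl1 (limma adjusted p = 0.02), and 10 had one adjusted over the 28 alone, all positive and all lower in MSC veins, among them Adcy5, Arxes2, Net1, Smoc1, Acss3, Tshr and Fgl1. The other 18 had none, among them Cyp2e1, Cish, Irf4, Gpc1, Sqle and Rgs14, which with 5 residual degrees of freedom does not exclude one.

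The 3 genes that rose were Gpc1, a heparan sulfate proteoglycan of the cell surface, Sqle, a rate-limiting enzyme of cholesterol synthesis, and Rgs14, a regulator of G-protein signalling. Gpc1 rose from 3.82 ± 0.411 to 7.55 ± 0.820 RPKM (SD, n = 4 each; log2 fold change 0.82, SE 0.09, limma adjusted p = 0.0233). Sqle rose from 4.06 ± 0.441 to 7.93 ± 1.39 RPKM (log2 fold change 0.81, SE 0.12, limma adjusted p = 0.0446), and Rgs14 had a log2 fold change of 0.45 (SE 0.07, limma adjusted p = 0.0484). Next by unadjusted p came Parvg and Card9, both genes of leukocytes, with log2 fold changes of 0.66 and 0.41. Neither passed (limma adjusted p = 0.0534 and 0.0535).

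In GRCm38 coordinates, the protein-coding gene Cyp2e1 spans 140763739 to 140774987 on chromosome 7 and Acsl1 spans 46471037 to 46536051 on chromosome 8. Irf4 lies at 30749226 to 30766976 on chromosome 13, Sqle at 59315077 to 59331192 on chromosome 15, and Gpc1 at 92831645 to 92860779 on chromosome 1. An exon of Gpc1 overlaps Ankmy1 on the opposite strand, and exons of Acss3, Cish and Card9 likewise overlap Ppfia2, Gm17041 and Gm13562. The same applies to Gapdh, Gpi1, C2, Sox17, Il1b, Ctgf, Des, Nos3, Fn1, Col4a1 and Hif1a, printed below, and exons of Ctsd, S100a4, C2 and Hif1a overlap another gene on the same strand. Reads of such pairs cannot be told apart where strand was not used or is shared, so these values are uncertain.

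**Figure D2:**
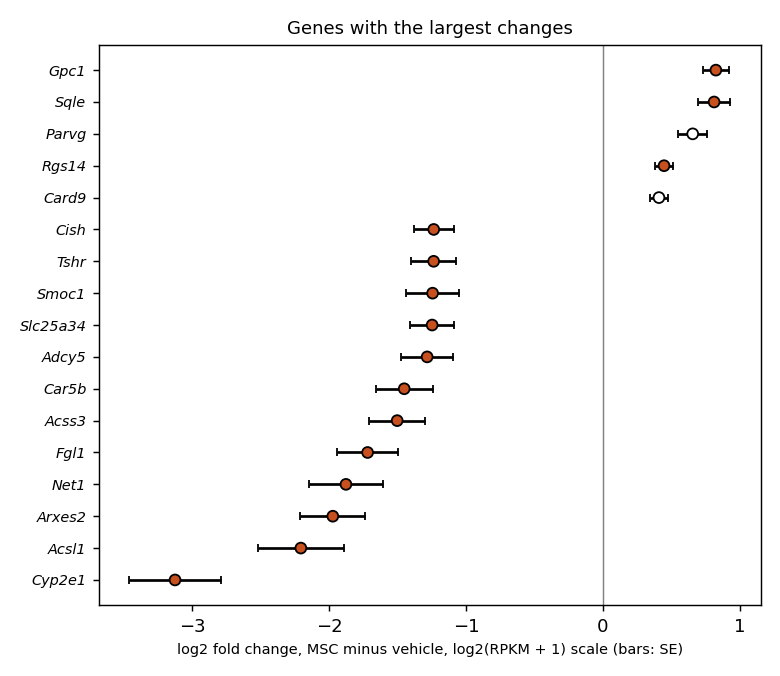
Log2 fold changes, MSC minus vehicle, on the log2(RPKM + 1) scale for the named genes with the largest changes, with bars of 1 SE from limma. Filled points passed an adjusted p of 0.05 and open points (Parvg, Card9) did not; Cyp2e1 at -3.12 lies farthest from 0.

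How many genes passed depended on single samples. Leaving out MSC replicate 4 or vehicle replicate 2 left 0 of the 28 (1554 and 1513 genes had an unadjusted p under 0.05), and leaving out MSC replicate 3 gave 171. With all samples, 1998 genes had an unadjusted p under 0.05, 1227 higher and 771 lower, and the groups did not overlap in 1186 genes (9.78%, where chance gives 2.86%).

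Genes of fat cells made up the gene list with the largest difference. Fabp4, the fatty acid carrier of adipocytes, averaged 530 ± 363 RPKM in MSC veins and 1990.6 ± 318 in vehicle veins (SD, n = 4 each; log2 fold change -2.17, limma adjusted p = 0.0719). Lpl, which releases fatty acids from lipoproteins, had -1.25, the triglyceride lipase gene Pnpla2 had -1.95 and Retn, which encodes resistin, had -2.55. Of 25 adipocyte genes tested, 24 had a negative log2 fold change, with a median of -1.54. None passed over all genes in limma and 22 fell adjusted over the list alone. The list fell against other genes by camera (adjusted p = 2.8e-17), a call lost with an estimated correlation (adjusted p = 0.913). Its mean score was 4.07 ± 0.85 in MSC and 5.53 ± 0.30 in vehicle samples (SD, n = 4 each, exact permutation p = 0.0286, adjusted over lists 0.286).

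Camera called 11 of the 40 lists, 6 higher and 5 lower. All 11 had an adjusted p = 0.913 with an estimated correlation, and fry's directional test gave no list an adjusted p below 0.22. That shared 0.913 covers unadjusted camera p from 0.0442 for adipocyte genes to 0.470 for endothelial markers. By fry's test for change in either direction, 13 lists passed. Over the 40 lists, 1 gene passed over all genes, Tshr, in the salivary and thyroid list.

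Monocyte and macrophage markers were higher in MSC veins, with a median log2 fold change of 0.25 over 29 genes (camera adjusted p = 0.000408; adjusted p = 0.913 with an estimated correlation). Adjusted over the list alone, 4 rose: Ctsd, a lysosomal protease (0.46), Gpnmb (0.63), Spp1, which encodes osteopontin (1.32), and the macrophage marker Cd68 (0.46), all as log2 fold changes. The list's score was 7.05 ± 0.17 in MSC and 6.75 ± 0.09 in vehicle samples (SD, n = 4 each, exact permutation p = 0.0286, adjusted over lists 0.286). The adipocyte score moved with the groups beside it, lower in all 4 MSC samples, and 8 of the 29 genes are also in other lists. With the adipocyte score as a covariate the median was 0.0988, against 0.103 over all genes in that fit (0.0404 without the covariate). Camera compares a list with other genes, and its direction reversed, though the median stayed above 0. The list was not called (camera adjusted p = 0.745). Adipocyte scores ran from 3.30 to 4.99 in MSC and from 5.19 to 5.90 in vehicle samples, so that fit extrapolates between groups.

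Inflammatory cytokines and NF-kB targets had a median of 0.29 over 28 genes (camera adjusted p = 0.0282, and adjusted p = 0.913 with an estimated correlation). Adjusted over the list alone, 4 rose: the interleukin-6 family cytokines Lif (0.93) and Osm (0.99), Ier3 (0.86) and the macrophage growth factor gene Csf1 (0.37). The list's call was lost without MSC replicate 1 (adjusted p = 0.257), without vehicle replicate 3 (0.304), with sample weights (0.129) and with the adipocyte or skeletal muscle score as a covariate (0.139 and 0.315). Neutrophil markers had a median of 0.57 over 20 genes (camera adjusted p = 0.0131, and adjusted p = 0.913 with an estimated correlation), with no member past either adjustment. Of its members 18 were above 0, among them Csf3r, the receptor for granulocyte colony-stimulating factor (0.79), and 2 were below, Lcn2 (-1.29) and 1100001G20Rik (-1.68). This call was lost without MSC replicate 1 (adjusted p = 0.251), without vehicle replicate 3 (0.156), with no filter on low values (0.0882), with sample weights (0.146) and with the skeletal muscle score as a covariate (0.213).

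Cell cycle genes had a median of 0.23, with 39 of 40 members above 0 and none past either adjustment (camera adjusted p = 2.34e-06, and adjusted p = 0.913 with an estimated correlation). The groups overlapped in the list's score (exact permutation p = 0.114). Vehicle replicate 3 stood at 3.85 and MSC replicates 1 to 4 at 3.56, 3.71, 3.78 and 3.90. E2f1, a transcription factor of S-phase entry, had a log2 fold change of 0.51 and Mcm3, part of the replicative helicase, had 0.50. Hypoxia and glycolysis genes had a median of 0.27 over 30 genes (camera adjusted p = 0.0114, and adjusted p = 0.913 with an estimated correlation). The call was lost without vehicle replicate 1 (median 0.13, adjusted p = 0.0680), without MSC replicate 1 (adjusted p = 0.223), with sample weights (median 0.16, adjusted p = 0.255) and with the adipocyte score as a covariate (adjusted p = 0.582). Adjusted over the list alone, 7 rose, among them the glycolytic enzyme genes Pkm2 (0.68), Gapdh (0.57) and Gpi1 (0.47), and 1 fell, Vegfa (-0.55).

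Complement genes had a median of -0.35 over 21 genes (camera adjusted p = 0.00986, and adjusted p = 0.913 with an estimated correlation). Adjusted over the list alone, 6 fell, among them C4b (-1.39), C2 (-0.83) and C3 (-1.12), and 1 rose, the leukocyte integrin gene Itgb2 (0.55). Another of the 6, Cfd (-2.31), is also in the adipocyte list, whose score was lower in the same samples. Without vehicle replicate 1 the complement call was lost (median -0.27, adjusted p = 0.0815). Fibroblast and adventitial markers had a median of -0.15 over 24 genes (camera adjusted p = 0.0266) and endothelial markers one of -0.09 over 29 genes (camera adjusted p = 0.0301); each had an adjusted p = 0.913 with an estimated correlation. The fibroblast median was 0.0249 without vehicle replicate 1 (camera adjusted p = 0.448), against 0.0264 over all genes. The endothelial median was 0.00283 without MSC replicate 1 (camera adjusted p = 0.358), against 0.0583 over all genes. Each median thus changed sign and each call was lost without a single sample, while camera's direction against other genes stayed lower. With the adipocyte score as a covariate, camera's direction for endothelial markers reversed (median 0.45, adjusted p = 4.61e-06). Adjusted over the list alone, 1 gene fell in each of the fibroblast and endothelial lists: Gsn (-0.88), which severs actin, and Sox17 (-0.61), a transcription factor of arterial endothelium. The 4 Y-linked genes of the sex-linked list had a median of -0.16 (camera adjusted p = 0.0299, and adjusted p = 0.913 with an estimated correlation), with Ddx3y at -0.28. That call was lost without MSC replicate 2 (adjusted p = 0.0671), vehicle replicate 2 (0.0514) or vehicle replicate 3 (0.0543). It was also lost with the skeletal muscle score as a covariate (adjusted p = 0.0955).

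Skeletal muscle genes differed widely between samples of the same group. The median was 1.21 over 28 genes (camera adjusted p = 0.00154, and adjusted p = 0.913 with an estimated correlation), and no member passed either adjustment. The call was lost without vehicle replicate 3 (median 0.75, adjusted p = 0.292) and without MSC replicate 1 (median 0.96, adjusted p = 0.192), and the median reached 2.11 with voom. Acta1, the skeletal muscle actin gene, singled out after its values were seen, was at 140, 11.9, 0.317 and 23.8 RPKM in vehicle replicates 1 to 4 and at 171, 230, 188 and 2.10 in the MSC replicates. Scores averaged 3.40 ± 1.65 in MSC and 2.16 ± 1.33 in vehicle samples (SD, n = 4 each, exact permutation p = 0.286).

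**Figure D3:**
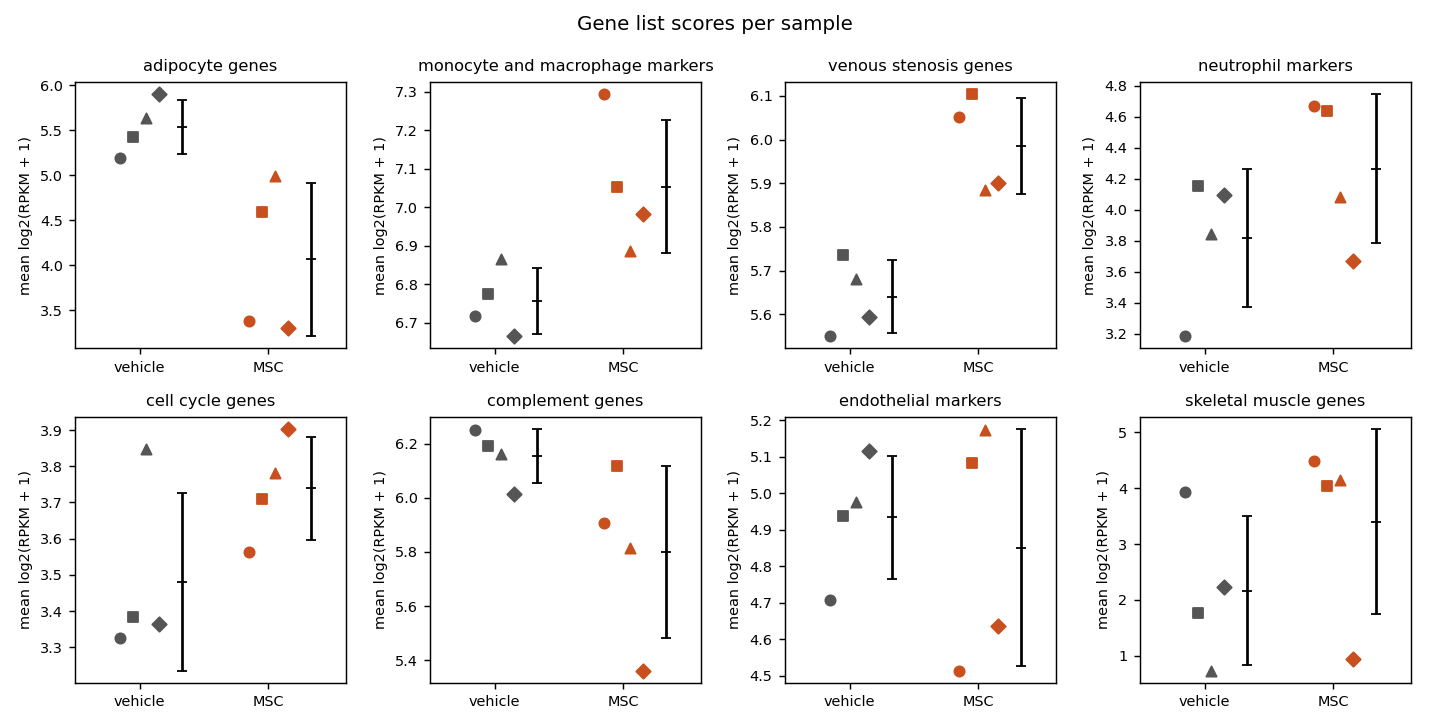
Mean log2(RPKM + 1) of 8 gene lists, 1 point per sample (circle, square, triangle and diamond for replicates 1 to 4), with bars for mean and SD of 4 samples; the axes do not start at 0. The groups do not overlap for adipocyte, monocyte and macrophage, and venous stenosis genes, and MSC replicate 4 stands at 0.94 in skeletal muscle genes.

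The venous stenosis list, genes that earlier work ties to narrowing of the fistula vein, was not called by camera (median 0.31 over 25 genes, camera adjusted p = 0.0587). All 25 of its genes are also in other lists. Whether it was called depended on the processing: 9 alternatives called it, with camera adjusted p from 0.0141 (without vehicle replicate 2) to 0.0496 (without MSC replicate 2). With all samples the list had an adjusted p = 0.913 with an estimated correlation and a fry adjusted p = 0.22. It passed fry's test for change in either direction (adjusted p = 0.000728), and its score was 5.99 ± 0.11 in MSC and 5.64 ± 0.08 in vehicle samples (SD, n = 4 each, exact permutation p = 0.0286, adjusted over lists 0.286). No member passed over all genes. Adjusted over the list alone, 4 rose: Ier3, the matrix metalloprotease gene Mmp9 (1.29), Cd68 and Fn1, which encodes fibronectin (0.46). Also adjusted over the list alone, 3 fell: the angiogenic factor gene Vegfa (-0.55), the basement membrane collagen gene Col4a1 (-0.66) and Myh11, the smooth muscle myosin (-0.75). Vegfa averaged 20.8 ± 2.75 RPKM in MSC and 30.9 ± 2.32 in vehicle veins (SD, n = 4 each; limma adjusted p = 0.0608), and Ier3 averaged 63.0 ± 17.6 and 33.9 ± 6.95 (limma adjusted p = 0.0944).

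The remaining genes of that list did not pass either adjustment. Among cytokine and growth factor genes, log2 fold changes were 1.59 for Il1b, 0.81 for Tnf, 0.58 for Il6, 0.31 for Ccl2, 0.36 for Tgfb1, 0.43 for Pdgfb and 0.29 for Ctgf. Matrix and protease genes had 0.31 for Col1a1, 0.33 for Timp1, 0.06 for Mmp2 and 0.04 for Adamts1. Among markers of contractile, fibroblast-like, endothelial and dividing cells, Acta2 had 0.21, Des 1.55, S100a4 0.20, Nos3 -0.22 and Mki67 0.22. Des varied between samples much as the skeletal muscle gene Acta1 did. It was at 32.6, 7.78, 6.21 and 11.3 RPKM in vehicle replicates 1 to 4 and at 48.3, 64.3, 51.9 and 10.2 in the MSC replicates. Its difference therefore cannot be assigned to contractile cells of the vein. Hif1a, the hypoxia-inducible transcription factor, had 0.16.

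**Figure D4:**
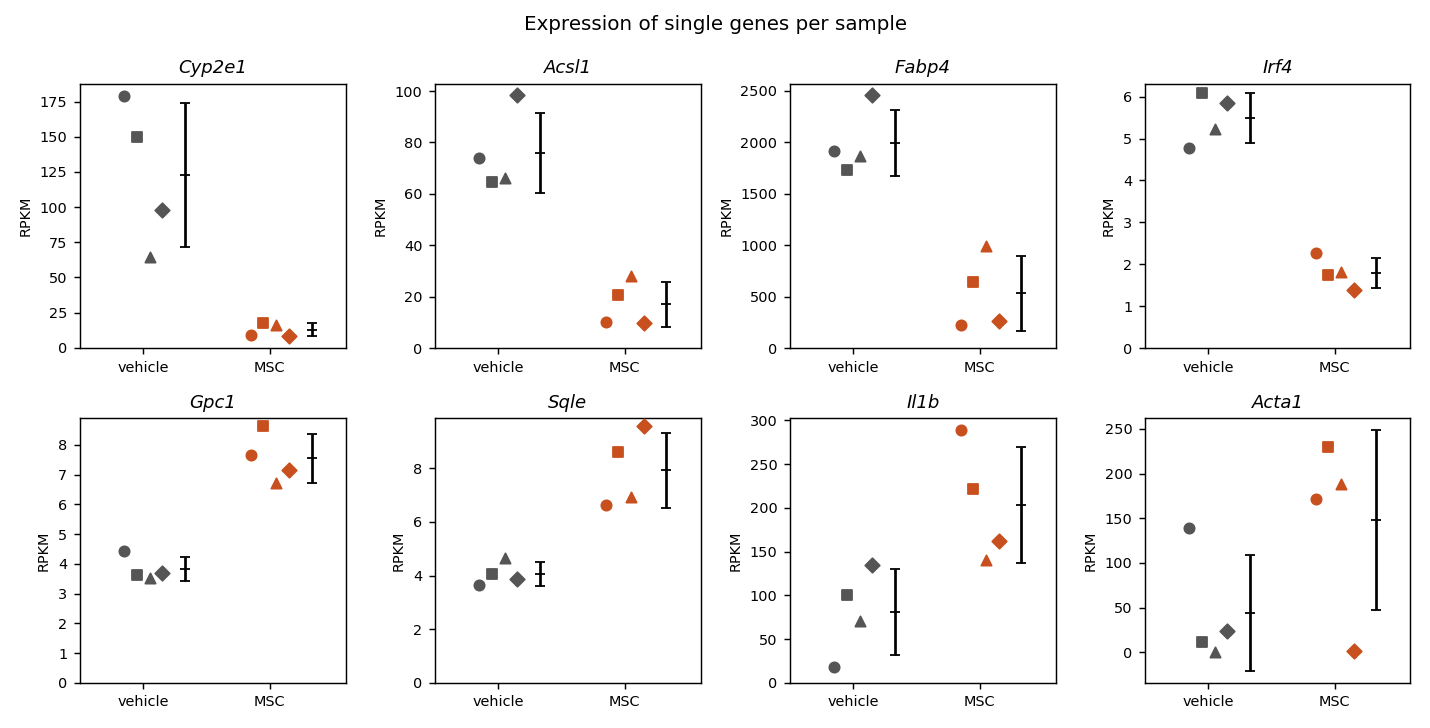
RPKM of 8 genes, 1 point per sample (circle, square, triangle and diamond for replicates 1 to 4), with bars for mean and SD of 4 samples. Acta1 separates replicates within both groups, with MSC replicate 4 at 2.10 and vehicle replicate 1 at 140, whereas Cyp2e1, Acsl1, Irf4, Gpc1 and Sqle separate the groups.

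The other 28 lists tested were not called by camera. Some held members that passed adjusted over the list alone. In contractile smooth muscle genes (median 0.01) 2 rose, the tropomyosin genes Tpm1 (0.56) and Tpm2 (0.81), and 4 fell, among them the pericyte marker Rgs5 (-1.28). Skeletal muscle also expresses tropomyosins: with the skeletal muscle score as a covariate, the log2 fold change of Tpm2 was 0.60 and that of Tpm1 was 0.56. In antigen presentation by MHC (median -0.05) 4 fell, among them H2-Q6 (-1.02), whose reads can be shared with its paralogs, and B2m (-0.42). That list was called lower in 5 alternatives, among them without vehicle replicate 1 (median -0.14, camera adjusted p = 0.00282). With all samples it had an adjusted p = 0.913 with an estimated correlation. In oxidative stress defence (median 0.15) 1 rose and 1 fell, Cat (-1.08), which encodes catalase. Medians with members passing in the list alone were 0.36 for B cell and plasma cell markers (2 rose), -0.03 for T and NK cell markers (1 rose) and -0.04 for angiogenesis factors (1 fell). They were -0.21 for haemoglobin and red cell genes (1 fell), 0.17 for Schwann cell and nerve genes (2 fell), -0.38 for salivary and thyroid gland genes (2 rose, 2 fell) and -0.06 for osteogenic and chondrogenic genes (1 rose).

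In the rest no member passed either adjustment. Median log2 fold changes of immune lists were 0.27 for chemokines, 0.04 for alternatively activated macrophage genes, -0.02 for dendritic and mast cell markers, -0.15 for interferon response genes and 0.31 for platelet and megakaryocyte genes. The interferon median moved with single samples: it was -0.51 without vehicle replicate 1 (camera adjusted p = 2.13e-07), -0.30 without vehicle replicate 3 (camera adjusted p = 0.00248) and -0.47 with sample weights (camera adjusted p = 6.9e-06). With all samples this list had an adjusted p = 0.948 with an estimated correlation and a fry adjusted p = 0.886. Its scores overlapped (exact permutation p = 0.771): 3.25, 5.24, 3.88 and 4.73 in vehicle replicates 1 to 4 and 3.76, 4.33, 4.09 and 4.31 in the MSC replicates. The settings printed are those that deepened the fall, whereas vehicle replicate 2, with the highest score, weighs toward it. Matrix and signalling lists had 0.14 for matrix proteases and inhibitors, -0.0038 for collagens and matrix structural genes, 0.11 for TGF-beta signalling, 0.01 for Wnt and Notch signalling and 0.04 for coagulation and fibrinolysis genes. The collagen median was -0.20 without vehicle replicate 4 (camera adjusted p = 0.0193) and -0.20 with the adipocyte score as a covariate (camera adjusted p = 4.61e-06). With all samples and no covariate that list had an adjusted p = 0.950 with an estimated correlation. Stress and housekeeping lists had 0.11 for apoptosis and p53 target genes, 0.05 for the ER stress and unfolded protein response, 0.19 for immediate early and heat shock genes, -0.07 for oxidative phosphorylation genes and 0.07 for ribosomal protein genes. Markers of other tissues had -0.11 for lymphatic endothelium, 0.37 for cardiac muscle and 0.06 for surface markers of mesenchymal stromal cells.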

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

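All explanations weighed in this part, and the tests of them, were chosen after the results were seen. A sample was set apart when its gap to the nearest of its group relative to the group's range exceeded Dixon's critical value for 4 values at 0.05; 19 of 248 groups of 4 values met this, where chance gives about 1 in 20. Values are log2(RPKM + 1), for lists the mean over members.

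MSC replicate 4 stood below its group in skeletal muscle genes (0.94, others 4.04 to 4.48), Acta1 (1.63), Des (3.49), Lcn2 (3.27), Ly6a (7.94) and Ccl2 (6.94). Vehicle replicate 3 stood above its group in cell cycle genes (3.85, others 3.33 to 3.38), Mki67 (4.55) and platelet and megakaryocyte genes (3.83, others 3.10 to 3.14). Vehicle replicate 4 was high in dendritic and mast cell markers (3.60) and low in lymphatic endothelial markers (3.26) and Fn1 (7.36). MSC replicate 2 was high in mesenchymal stromal cell surface markers (5.65), and MSC replicate 1 was high in Parvg (3.58) and low in Sox17 (0.48). Vehicle replicate 1 was low in Lif (0.89) and high in Nos3 (4.97), vehicle replicate 2 was high in Il6 (4.44), and MSC replicate 3 was low in Fn1 (7.83).

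Chance cannot be excluded for the counts of changed genes and lists. Of the 35 splits of the 8 samples, 2, the real one included, gave as many changed genes. The real split gave 28, of which 3 were higher and 25 lower, and the highest of the others gave 70, all in 1 direction. The split with 70 reached the count of each direction taken alone, but not both together. That other split, vehicle replicate 1 with MSC replicates 1, 2 and 3 against the rest, points to a structure of the samples, since 62 of its 70 genes follow the skeletal muscle score with a correlation above 0.9, and it shared 0 genes with the real calls. As many lists as the real 11 came from 30 of the 35 splits, the real one included, and the highest other split gave 26. For genes at an unadjusted p under 0.05, the real split gave 1998, more than any other split (at most 1665).

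Adipocyte genes were lower in all 4 MSC samples. Dilution by the RNA of arriving leukocytes would lower the other resident cells' markers as much, but the median log2 fold change of 77 endothelial, smooth muscle and fibroblast markers was -0.0704 (SD 0.41 over markers) against -1.54, which argues against it. Less fat tissue in the MSC samples may also lower these genes. It would keep them in one ratio only if fat cells were their sole source and all lay well above the pseudocount. Of 22 members, 0 fell by more than Adipoq, Plin1 and Cidec, and 10 fell by less or, as Acly (0.14), did not go down. Members falling by less do not argue against less fat tissue, so it stays open. Why these 10 differed was not tested. Of them, Lep and Cidea averaged 1.23 and 1.14 RPKM in vehicle samples, where a pseudocount of 1 limits the fall. As first written this test looked only at members falling by more and read as fitting; the condition on members falling by less was added after that result was seen. Adipoq itself was at 171, 279, 224 and 379 RPKM in vehicle and 28.1, 117, 154 and 17.5 in MSC samples, and 1 of the 25 members is also in another list. Fat content and treatment cannot be told apart here, since they go with the same groups, and an effect of the cells on adipocytes is untested.

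Monocyte and macrophage markers were higher in all 4 MSC samples. Loss of fat RNA would raise every other cell's markers alike. The macrophage score gained 0.38 over the score of the 77 resident markers (exact permutation p = 0.0286, 2-sided, the smallest possible). This cannot decide, since the resident markers may themselves go down with fat. With the adipocyte score as a covariate the endothelial median was 0.45 (camera adjusted p = 4.61e-06), against -0.09 without it. With that covariate the macrophage median was 0.0988 (0.103 over all genes) and the macrophage call was lost (camera adjusted p = 0.745), so the explanation stays open. More blood in the MSC samples may raise leukocyte genes: the haemoglobin and red cell list had a mean log2 fold change of -0.18 with an upper 95% bound of 0.26, against the macrophage median of 0.25, so it stays open. Values against it are that camera called this list lower in 4 alternatives, with the lowest adjusted p = 0.00655 without vehicle replicate 1 (median -0.39). With all samples its adjusted p was 0.913 with an estimated correlation. This test was first run on Beta-s alone (log2 fold change -0.55, not passing), the only haemoglobin chain gene above 10 RPKM that it took, and then argued against more blood. It was widened to the list after that result was seen, because 1 gene was thought too few. An effect of the treatment is untested beyond the comparison itself.

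Skeletal muscle genes differed between samples of both groups. Neck muscle carried along in the dissection is a candidate source, and would move muscle genes in one ratio. The median correlation of a member with the mean of the others was 0.97 over 8 samples and 28 genes, and the lowest was -0.0192. Any shared change of muscle genes would also give a high correlation, so this cannot single out carried-along muscle. Higher muscle gene expression after MSC treatment would not make vehicle samples differ. Their scores were 3.93, 1.76, 0.73 and 2.22 in replicates 1 to 4, which argues against treatment as the source of the differences within groups. Whether treatment also raised the group mean was not decided by the exact permutation test of the score (p = 0.286). For the difference between group means, these 2 explanations are not exclusive, and the design does not separate them.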

How the results depend on the processing

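Voom, the 2 score covariates and the fit without muscle-following genes were chosen after the data were seen. Separation of the groups kept p = 0.0286 in each alternative run for it, including each sample left out and a Spearman distance. In every alternative that tested all 28 genes called, all 28 kept their direction, but their number did not hold, and the cause was not tested except where named. In limma, changed genes (higher, lower) numbered 10 (1, 9) with a pseudocount of 0.1, 1 (1, 0) with no filter on low values, 129 (33, 96) after quantile normalization, 72 (11, 61) with median-of-ratios scaling, 51 (9, 42) rescaled to TPM and 73 (27, 46) with sample quality weights. Quantile normalization thus lowered the share of lower genes among those called from 89.3% to 74.4%, while their number rose from 25 to 96. With sample quality weights that share was 63.0%. A mean of at least 5 RPKM gave 6 higher, an adjusted p under 0.10 gave 225 (80, 145), and at least a 2-fold change left 17 (0, 17), by construction. Voom on recovered reads gave 37 genes, 6 of them higher, and 27 of the 28 calls were shared. With the skeletal muscle score as a covariate 61 (10, 51) passed, without the 83 genes that follow skeletal muscle 57 (8, 49), and with the adipocyte score as a covariate 0 (0, 0; 816 at an unadjusted p under 0.05). Other alternatives stayed within 1.5 times of 28.

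Without MSC replicates 1 to 4 the counts were 3 (1, 2), 5 (0, 5), 171 (31, 140) and 0 (0, 0), and without vehicle replicates 1 to 4 they were 17 (4, 13), 0 (0, 0), 1 (0, 1) and 8 (0, 8). The effect of a single sample was not separated from that of a smaller group. The groups share replicate numbers, but deviations of same-numbered samples correlated at 0.14, -0.0028, -0.33 and -0.12, which gives no sign of pairing. With the replicate block 0 genes passed in limma (0 higher, 0 lower; 1768 at an unadjusted p under 0.05) and 14 lists were called; 1 of the 4 MSC samples correlated best with its own number.

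The 11 lists became 0 with an estimated inter-gene correlation (1 list at an unadjusted p under 0.05) and 0 by fry (5 lists), and 8 to 15 when 1 sample was left out. Cell cycle genes kept their call in 22 of 24 alternatives, adipocyte, macrophage and complement genes each in 21, fibroblast, hypoxia and sex-linked genes each in 18, inflammatory and neutrophil genes each in 17, endothelial markers in 13, and skeletal muscle genes in 18 of 23. The endothelial call was lost under quantile, median-of-ratios and TPM scaling, among others. Of lists not called, the venous stenosis, interferon, antigen presentation, haemoglobin, collagen, oxidative phosphorylation, matrix protease, immediate early, B cell, angiogenesis, ribosomal and Schwann cell lists were each called in at least 1 alternative, all at the preset correlation. With the adipocyte score as a covariate the median over all genes was 0.103. Camera's direction then reversed for macrophage markers (median 0.0988, not called), endothelial markers (0.45, called) and immediate early and heat shock genes (-0.0375, called). Under the skeletal muscle score as a covariate camera's direction reversed for skeletal muscle genes (0.0074, not called), by construction. Among genes taken by the naming rule or printed, calls were lost in 172 pairs of gene and setting, gained in 79 and reversed in 0.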

Other observations

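The lists and tests in this part were chosen after the data were seen. Enzymes that oxidise fatty acids and that break down branched-chain amino acids were lower in MSC veins. Among 25 fatty acid oxidation genes 24 had negative log2 fold changes (median -0.43) and 2 passed over all genes in limma, Acsl1 and Ehhadh (-1.03); adjusted over the list alone, 19 fell. Among 24 genes of branched-chain amino acid breakdown all 24 had negative values (median -0.47), and Dbt (-0.79) passed over all genes; adjusted over the list alone, 18 fell. Both lists separated the groups (exact permutation p = 0.0286, the smallest possible). By camera with an estimated correlation both had an adjusted p = 0.0627, adjusted over the lists of this part alone. Their unadjusted p by that test was 0.0354 and 0.0418. The adipocyte list had 0.0442 unadjusted, and its 0.913 was adjusted over 40 lists, so the adjusted values cannot be compared. Their direction is that of the adipocyte list. They were written down after Acsl1, Ehhadh and Dbt had been seen to fall, so they are not independent evidence.

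Cholesterol synthesis genes went the other way. Of 24 genes 23 had positive log2 fold changes (median 0.35), among them Sqle (0.81), Fdps (0.74), Cyp51 (0.64), Fdft1 (0.63) and the regulator Srebf2 (0.48), and Acat2 (-0.61) was the exception. Only Sqle passed over all genes in limma; adjusted over the list alone, 16 rose and 1 fell. The list's adjusted p by camera with an estimated correlation was 0.0723, adjusted over the lists of this part alone. A coordinated rise of sterol synthesis genes may underlie this, and was tested on the 16 members not among those noticed first: 15 were higher, with a mean difference of 0.22 (exact permutation p = 0.0571, 2-sided), which leaves the hypothesis open.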
